A study of Rattus norvegicus with 8 samples.

How the data were processed

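RNA was measured in 8 libraries of primary rat oligodendrocyte precursor cells, 4 from male and 4 from female animals. Per the labels' protocols, mixed glia of 1 to 2 day old Sprague Dawley rats were grown in DMEM with 20% serum. The precursor cells were taken as the non-adherent fraction and grown in Neurobasal medium with the supplement B27 (2%) and the growth factors FGF and PDGF, each at 10 ng/ml, for 4 to 5 days. Total RNA was made into libraries with a strand-specific Agilent SureSelect kit and sequenced on an Illumina MiSeq. The sex and number of each library were taken from its title, and sex is the only factor the labels give.

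The authors deposited a table of FPKM values, 1 per gene and library, as the column names in the file header state. Trimmomatic and FastQC are named in the submitters' processing notes, without versions. The aligner, the program that made the FPKM values, the genome build, the annotation release and the use of strand in counting are not given in the sources used here. FPKM divides by library size, so a rise of a few abundant genes lowers all others, and it holds no counts. The deposited FPKM values summed to between 648383 and 773919 per library. Low values fell in steps, each taken as worth 1 fragment, and the steps gave the depth of each library relative to male 1, from 0.303 to 1. After scaling by the steps, 87.9% of 4569 low values were whole multiples, within 0.05, of the lowest value of the same gene. The steps were fitted to low values too and equal values count as whole multiples, so part of this share is built in. Reads were not recovered from these steps. Shallower libraries measure low genes with more error, and no interval from counts could be given.

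The plan made before the data were examined was a count-based test, with limma-trend on log2 values as the stated fallback for a table without counts. As the table holds FPKM, the fallback was used. Values were taken as log2(FPKM + 1), and the 11263 of 32883 genes with a mean of at least 1 FPKM over the 8 libraries were kept. The test was limma (version 3.58.1 in R 4.3.3) with a mean-variance trend and robust moderation, with Benjamini-Hochberg adjustment over all tested genes and an adjusted p threshold of 0.05. Differences are male minus female. A gene is said to be called when it passed, and its values are said not to overlap when all 4 libraries of one sex lie above all 4 of the other. Symbols were matched to the RefSeq gene table of assembly GRCr8 to find X and Y genes. Of the tested genes 9991 matched by symbol, 453 by an older name and 819 by neither. Mitochondrially encoded genes were known by their symbols.

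Gene lists (31) were written before the data were examined, for lineage stage, cell cycle, metabolism, stress, signalling and other cell types that such cultures can hold. The 27 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27, and again with camera with an estimated correlation and with fry. With the preset correlation 14 lists passed, 9 towards male and 5 towards female cultures, and with the estimated one 1 passed. By fry 12 passed. A score per library was the mean z score of the members, compared by an exact two-sided permutation test over 70 assignments. For 12 lists the scores of the sexes did not overlap, and none passed after adjustment over the 27. Principal components were taken from the 500 most variable genes outside the X and Y lists.

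Genes are named by a rule set beforehand. It takes the 10 largest differences in each direction among called genes without overlap, the 10 smallest p outside the X and Y lists, the X and Y list genes, up to 4 members with the smallest p of each list, and a fixed set with Pdgfra, Cspg4, Olig2, Sox10, Mbp, Myrf, Mki67, Gfap, Aif1 and Esr1. Some genes that the rule takes are not reported here. Genes named outside it were chosen after their values were seen and are marked so. Among 98 named genes that were called, 65 kept their call with each library left out in turn and 33 lost it with at least 1 library left out. Most named genes were picked for large differences or small p, so this share need not hold for all called genes. Of all 680 called genes, 283 kept their call without male 3, the fewest, and 600 without female 3, the most.

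The test was run on simulated data with 200 of 11263 genes changed in each of 5 runs. It recovered 34.6% of genes changed by 0.5 on the log2 scale, 76.1% at 1 and 96.4% at 2, and 3.64% of its calls were false. A list of 39 genes shifted by 0.3 was called in 5 of 5 runs and other lists in 0 of 130 tests. Genes were drawn independently of one another, so false calls of lists whose genes vary together were not tested.

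Alternatives planned were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, quantile normalization, the replicate number as a block, an adjusted p threshold of 0.1, a test against a 1.5-fold change, each library left out in turn, 2000 genes for the components, and the other set tests. Those chosen after seeing the data were leaving out male 1 and female 3 together, a batch term for these libraries, relative depth as a covariate, and rescaling to the same total over genes that are not mitochondrially encoded. For the lists, named genes and the X-linked set, the pseudocounts and quantile normalization were also added then, and for that set no filter and the replicate block as well. The alternatives planned for counts could not be run on FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Xist was not analysed here.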

Results

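Gene expression was measured by RNA sequencing in cultured rat oligodendrocyte precursor cells (OPCs), the dividing glial cells that give rise to the myelin-forming cells of the brain. The cells came from the cerebral cortex of newborn Sprague Dawley rats. They were grown as mixed glia, collected as the cells that do not stay attached, and kept for 4 to 5 days with the growth factors PDGF and FGF, which hold OPCs in division. Cultures from male and from female animals were compared, with 4 libraries of each sex. Values were the authors' FPKM, which scales fragment counts by transcript length and library size, for 32883 genes. Between 12709 and 14014 genes were above 0 in each library. The absolute depth of the libraries is unknown. The steps between low values gave their depth relative to male 1, which was 0.553 in male 2, 0.769 in male 3, 0.557 in male 4, 0.303 in female 1, 0.366 in female 2, 0.981 in female 3 and 0.534 in female 4. Mean relative depth was 0.720 ± 0.212 (SD, n = 4) in the male and 0.546 ± 0.306 in the female libraries (exact two-sided permutation test, p = 0.343). Differences are given as male minus female on the log2(FPKM + 1) scale with their standard error, which understates the change of low genes, and levels as mean FPKM ± SD over 4 libraries, male against female. Nothing in the labels says that the libraries of one sex came from separate litters or animals, so p-values measure only the spread between these samples, which may be technical.

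Genes of the sex chromosomes followed the labels in all 8 libraries. The Y-linked translation factor gene Eif2s3y (ENSRNOG00000060048) was listed at 77.9, 76.6, 73.6 and 62.7 FPKM in male 1 to male 4 and at 0 in all 4 female libraries. Kdm5d (ENSRNOG00000060496), a Y-linked histone demethylase gene, was listed at 7.65, 7.81, 7.85 and 8.67 FPKM in male 1 to male 4 and at 0 in every female library. Other Y-linked genes (Ddx3y, Uba1y, Usp9y, Sry, Tspy1 and Rbmy1j) were at or near 0 in both sexes and were not tested. The symbol Ddx3 was listed at 5.12, 6.002, 6.54 and 6.23 FPKM in male 1 to male 4 and at 0 in the female ones. The RefSeq gene table of assembly GRCr8 gives that symbol to an autosomal gene and also holds it as an older name of Ddx3y, so its place is uncertain. Conversely, the unnamed gene Rn50_X_0752.3 was listed at 30.8, 18.2, 14.4 and 29.0 FPKM in female 1 to female 4 and at 0 in all 4 male libraries. Of 11 tested genes of the list of X inactivation genes and X-linked partners of Y genes, 3 were higher in female cultures and none in male ones, with 3 and 0 when adjusted over the list alone. They were Eif2s3 (118 ± 12.9 against 201 ± 9.83 FPKM, log2 difference -0.76 ± 0.08, limma-trend adjusted p = 0.00067), the histone demethylase gene Kdm5c (37.6 ± 3.70 against 57.5 ± 4.42 FPKM, -0.60 ± 0.09, adjusted p = 0.00443) and Kdm6a (4.34 ± 0.375 against 8.12 ± 1.81 FPKM, -0.75 ± 0.16, adjusted p = 0.0201). Kdm6a lost its call without male 2, male 3, female 1 or female 4 in turn (adjusted p up to 0.0679) and with relative depth as a covariate. Ddx3x (108 against 107 FPKM), Uba1 (209 against 223 FPKM), Usp9x (28.2 against 33.8 FPKM), Zfx (16.5 against 18.2 FPKM), Pbdc1, Txlng, Eif1ax and Mid1 were not called, with adjusted p from 0.242 to 0.960. As a set this list was lower in male cultures (median log2 difference -0.20, camera adjusted p = 0.00146; adjusted p = 0.129 with an estimated correlation). Its median was -0.13 without male 1 and -0.12 with relative depth as a covariate. The list was also lower in male 1 and female 3 than in the other 6 libraries (median -0.21, camera adjusted p = 0.0033). These libraries were picked because they deviate together in these same values. Here and below, p-values of that comparison are therefore only descriptive. The remaining 334 X-linked genes, tested to see whether X dosage shifts the chromosome as a whole, had a median log2 difference of -0.012 against -0.0034 for all other genes. The set was not past the threshold (camera p = 0.688; p = 0.805 with an estimated correlation), and the sign of its test was opposite to that of its median. Of these genes, 12 were higher in male and 7 in female cultures.

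Male and female cultures differed at 680 of 11263 tested genes (limma-trend, Benjamini-Hochberg adjusted p under 0.05), 354 higher in male and 326 higher in female cultures. Outside the X and Y chromosomes 656 genes differed, 340 higher in male and 316 in female cultures, of which 25 carry no chromosome in the RefSeq table. This count holds Ddx3 and Rn50_X_0752.3, whose places are uncertain. Differences were mostly small, and 107 of the 680 genes reached 2-fold on the log2(FPKM + 1) scale. The genes with the largest differences in male cultures included Egr1 (ENSRNOG00000019422), an immediate early transcription factor gene, at 75.8 ± 27 against 13.7 ± 4.04 FPKM (log2 difference 2.34 ± 0.33, adjusted p = 0.00786). Gad1 (ENSRNOG00000000007), which encodes an enzyme of GABA synthesis, stood at 19.2 ± 1.77 against 3.93 ± 1.12 FPKM (2.05 ± 0.16, adjusted p = 7.33e-05). Egr2, Dync1i1, Eef1a2, Tmem130 and LOC100361008 also belonged to this group, with log2 differences of 1.60 to 1.77. The histone gene Hist1h2ak was listed at 5.93, 4.92, 2.20 and 3.02 FPKM in male 1 to male 4 and at 0 in all female libraries, and reads of histone genes can be shared between near-identical copies. Female cultures were higher for Lyz2 (ENSRNOG00000005825), a lysozyme gene, at 2.21 ± 0.803 against 14.9 ± 3.48 FPKM (-2.32 ± 0.21, adjusted p = 0.000242), and for the complement genes C1qa, C1qb and C1qc. The receptor gene Gpr17, the lipid transfer gene Pltp, the Fc receptor subunit gene Fcer1g and the unnamed gene AABR07006310.1 also were among the largest differences in female cultures, between -1.65 and -1.83. The unnamed genes AABR07027407.1 (1.63 ± 0.33) and AABR07028795.1 (-2.89 ± 0.65) were in the same ranks, but the former lost its call without male 2, male 3 or female 4 (adjusted p up to 0.0629) and the latter without any single library but male 3 (up to 0.126). Fkbp1a, the gene of an immunophilin, was among the genes with the smallest p at 628 ± 23.2 against 363 ± 23.5 FPKM (0.79 ± 0.06, adjusted p = 7.33e-05). Of the 11263 genes, 1580 (14.0%) had male and female values that did not overlap, where chance gives 2.86%, and 664 of the 680 called genes were among them. The first principal component, from 500 genes, held 24.4% of the variance and separated the sexes, with scores of -12.1 ± 1.39 in male and 12.1 ± 5.37 in female libraries (exact two-sided permutation test, p = 0.0286, the smallest 70 assignments allow). For components 2 and 3 the test was not past the threshold (exact p = 0.8 and 0.943). Without male 1 and female 3 together that smallest p is 0.1, which is what the first component then gave. Leaving out one library changed the count of called genes by over 1.5 times, to 315 without male 2, 296 without male 3, 359 without male 4, 411 without female 1 and 318 without female 4. With relative depth as a covariate it was 367, and a test against a 1.5-fold change called 18. The libraries male 1 and female 3 deviated from their own groups in the same way (r = 0.408 over 6417 genes, which are not independent replicates), and without both the count was 882.

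**Figure D1:**
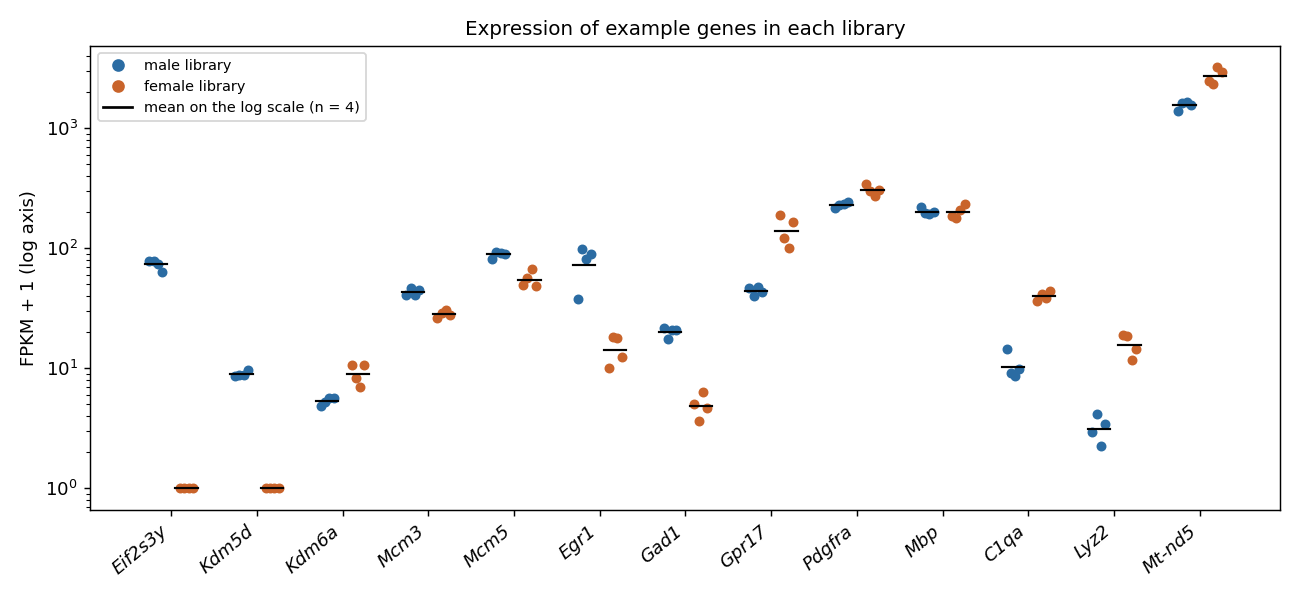
FPKM plus 1 (log axis) of 13 example genes in each library. Every point is one library, male on the left and female on the right, with a line at the mean on the log scale (n = 4), and Gad1 and Egr1 lie higher in all 4 male libraries, Gpr17, C1qa, Lyz2 and Mt-nd5 lie higher in all 4 female libraries, and Mbp overlaps.

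Genes of the G1/S transition and DNA replication were higher in male cultures. All 39 tested members had a positive log2 difference and 30 passed the test over all genes (38 adjusted over the list alone), with a median of 0.52. The flap endonuclease gene Fen1 stood at 39.5 ± 2.91 against 25.7 ± 1.09 FPKM (log2 difference 0.60 ± 0.08, limma-trend adjusted p = 0.00242). The replicative helicase genes Mcm3 (0.60 ± 0.08) and Mcm5 (0.70 ± 0.10) and the histone mRNA binding protein gene Slbp (0.65 ± 0.10) differed by similar amounts. Of 45 genes of G2/M and mitosis, all had a positive log2 difference and 14 passed (32 adjusted over the list alone), with a median of 0.31. Melk (0.59 ± 0.10, adjusted p = 0.00786) and Mybl2 (0.55 ± 0.11, adjusted p = 0.0131) were among them, as were Prc1 and Cdk1. Cdk1 stood at 232 ± 6.88 against 165 ± 26.9 FPKM. The proliferation marker Mki67 was not called (5.23 ± 0.563 against 3.90 ± 1.23 FPKM, adjusted p = 0.282). Both lists passed the set test (camera adjusted p = 2.2e-28 and 2.19e-17) and missed the threshold with an estimated correlation (adjusted p = 0.0863 and 0.129). Markers of microglia (median -1.43) and of neurons (median 0.28; camera adjusted p = 0.0863 with an estimated correlation) also differed between these cultures. Per library, the G1/S score was 0.453 to 0.955 in male and -1.16 to -0.295 in female cultures (exact two-sided permutation test, p = 0.0286, adjusted 0.0643 over 27 lists). G2/M genes were also higher in male 1 and female 3, picked for deviating together, than in the other libraries (median 0.088, camera adjusted p = 0.0033). The called members of the G1/S list numbered 18 without male 2, 18 without male 3, 19 without male 4 and 17 without female 4. Those of the G2/M list numbered 3 without male 2 or male 3, 4 without male 4, 6 without female 1 or with relative depth as a covariate, 8 without female 2, 2 without female 4 and 7 with no filter on low values. Prc1 lost its call without male 3, male 4 or female 4 and Cdk1 without male 2, male 3 or female 4 (adjusted p up to 0.0533).

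Immediate early genes and targets of ERK signalling were also higher in male cultures. Of 28 tested members 12 were higher in male and 1 in female cultures (16 and 1 adjusted over the list alone), with a median log2 difference of 0.40. Besides Egr1, the transcription factor gene Egr2 stood at 3.55 ± 1.48 against 0.278 ± 0.141 FPKM (1.77 ± 0.27, limma-trend adjusted p = 0.00515). The cyclin D1 gene Ccnd1 stood at 518 ± 44.4 against 327 ± 18.0 FPKM (0.66 ± 0.07, adjusted p = 0.00087), and Spry2, which encodes a feedback inhibitor of growth factor signalling, at 111 ± 6.03 against 74.9 ± 6.12 FPKM (0.56 ± 0.07, adjusted p = 0.00231). The exception was Myc, named after its value was seen, at 54.4 ± 7.19 against 75.3 ± 6.80 FPKM (-0.47 ± 0.10, adjusted p = 0.0209). Its call was lost without male 2, male 3, male 4, female 1 or female 4 in turn (adjusted p up to 0.0676) and with relative depth as a covariate. The list passed the set test (camera adjusted p = 1.36e-08; adjusted p = 0.0863 with an estimated correlation). Between the same cultures microglia markers had a median log2 difference of -1.43 and neuron markers one of 0.28 (camera adjusted p = 0.0863 for the latter with an estimated correlation). The male-higher members numbered 5 without male 2 or male 4, 4 without male 3 or with relative depth as a covariate, and 6 without female 1, female 2 or female 4.

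Female cultures had higher levels of OPC markers and of some genes that come on as OPCs begin to differentiate, while other genes of the latter list lay towards male cultures without being called. Of 25 OPC markers 9 were higher in female and none in male cultures (14 and 0 adjusted over the list alone), with a median log2 difference of -0.34. Gpr17, a receptor gene of precursors that are committed to differentiate, was 3.31 times as high in female cultures (43.1 ± 3.41 against 143 ± 40.3 FPKM, -1.66 ± 0.18, limma-trend adjusted p = 0.00126). The extracellular matrix gene Tnr (5.71 ± 0.995 against 17.8 ± 6.82 FPKM, -1.42 ± 0.25, adjusted p = 0.0111) and the transcription factor gene Sox8 (-0.57 ± 0.09, adjusted p = 0.00648) followed. The PDGF receptor gene Pdgfra stood at 229 ± 10.4 against 303 ± 27.8 FPKM (-0.40 ± 0.07, adjusted p = 0.0103). Sox10 was called (-0.35 ± 0.08, adjusted p = 0.0327), but lost its call without any single library except male 1 (adjusted p up to 0.102) and with relative depth as a covariate. Olig2 (258 ± 17.2 against 304 ± 11.7 FPKM, adjusted p = 0.0512) and Cspg4, the gene of NG2 (90.9 ± 10.6 against 118 ± 13.6 FPKM, adjusted p = 0.0554), missed the threshold. Among 36 genes of differentiating oligodendrocytes and myelin, 10 were higher in female and none in male cultures (14 and 1 adjusted over the list alone), with a median of -0.20. Myrf, the transcription factor gene that drives myelin gene expression, stood at 5.16 ± 0.907 against 14.0 ± 3.39 FPKM (-1.27 ± 0.18, adjusted p = 0.00351). The receptor gene Erbb3 (-1.26 ± 0.12, adjusted p = 0.000403), Bcas1 (142 ± 24.4 against 273 ± 39.5 FPKM, -0.94 ± 0.13, adjusted p = 0.00351) and Enpp2 (-0.68 ± 0.09, adjusted p = 0.00179) were also higher. The myelin basic protein gene Mbp was not called, at 200.4 ± 11.6 against 200.4 ± 25 FPKM (adjusted p = 0.976). On the male side were 10 of the 36, none of them called over all genes. They included Prr18 (7.54 ± 1.51 against 4.10 ± 2.05 FPKM, adjusted p = 0.0749) and the myelin genes Mog (3.73 ± 1.33 against 2.16 ± 0.766 FPKM, adjusted p = 0.205) and Mobp (4.89 ± 1.502 against 3.31 ± 1.75 FPKM, adjusted p = 0.399), all 3 named after their values were seen. Both lists passed the set test (camera adjusted p = 3.05e-10 and 2.07e-05), and with an estimated correlation neither did (adjusted p = 0.104 and 0.0863). In the same cultures microglia and macrophage markers were higher in female libraries (median -1.43) and neuron markers had a median of 0.28 (camera adjusted p = 0.0863 with an estimated correlation). OPC markers were also lower in male 1 and female 3, picked for deviating together, than in the other libraries (median -0.12, camera adjusted p = 0.0316). Called OPC markers numbered 4 without male 2, male 3, male 4, female 1 or female 4 and with relative depth as a covariate, 5 with no filter on low values, 15 without male 1 and female 3 and 14, with 1 higher in male cultures, when these were a batch term. The median of the differentiation list was -0.09 with no filter on low values and -0.34 at a mean of at least 5 FPKM, and without female 3, or without it and male 1, Prr18 was called as higher in male cultures.

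Markers of microglia and macrophages, the immune cells of the brain, which mixed glial cultures can hold, were higher in female cultures. All 17 tested members had a negative log2 difference and 14 passed (17 adjusted over the list alone), with a median of -1.43. By mean FPKM the median member was 3.55 times as high in female cultures. C1qa stood at 9.56 ± 2.70 against 39.05 ± 3.54 FPKM (-1.95 ± 0.15, limma-trend adjusted p = 7.33e-05), C1qb at 9.63 ± 0.938 against 33.5 ± 2.73 FPKM (-1.70 ± 0.10, adjusted p = 6.69e-06) and C1qc at 9.53 ± 2.21 against 36.2 ± 2.04 FPKM (-1.84 ± 0.14, adjusted p = 6.93e-05). The microglial marker Aif1 stood at 2.68 ± 0.948 against 8.57 ± 2.55 FPKM (-1.38 ± 0.23, adjusted p = 0.00654). This was the only list that passed the set test both with the preset correlation (camera adjusted p = 5.93e-21) and with an estimated one (adjusted p = 0.0194). List scores were -0.96 to -0.65 in male and 0.61 to 1.10 in female libraries. With a pseudocount of 5 the median was -0.81. Between the same cultures neuron markers had a median of 0.28 (camera adjusted p = 0.0863 with an estimated correlation). The astrocyte and Schwann cell lists were not past the threshold. In the astrocyte list 1 of 16 members was called, over all genes and adjusted over the list alone, Apoe (16.1 ± 4.08 against 32.8 ± 8.74 FPKM, adjusted p = 0.0314), which microglia also express and which lost its call without male 2, male 3, female 1, female 2 or female 4 (adjusted p up to 0.0975). The astrocyte marker Gfap was low in both sexes (2.39 ± 1.81 against 1.96 ± 2.13 FPKM, adjusted p = 0.754). The camera adjusted p of the astrocyte list was 0.868, and its median of 0.11 was opposite in sign to its test. In the Schwann cell list 2 of 7 members were called (2 adjusted over the list alone), Egr2 and Pmp22, with a camera adjusted p of 0.506, a median of -0.033 and a mean and test of the opposite sign. Pmp22 kept its call only with male 2 left out. Fewer than 5 genes of the endothelial, fibroblast and ependymal lists were above the filter. Among them Tagln, a smooth muscle gene (2.60 ± 0.727 against 0.570 ± 0.392 FPKM, adjusted p = 0.0182), and Igfbp2 (72.2 ± 10.5 against 30.9 ± 3.30 FPKM, 1.19 ± 0.11, adjusted p = 0.000299) were higher in male cultures and Prrx1 was not called. Tagln lost its call without male 2 or male 4 (adjusted p up to 0.0688).

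Some neuron and neuroblast markers were higher in male cultures, and among called members Gad1, Dlx1 and Gad2 differed most. Of 17 tested members 11 had a positive log2 difference, and 5 were called as higher in male and none in female cultures (6 and 0 adjusted over the list alone), with a median of 0.28. Besides Gad1, the GABA synthesis gene Gad2 stood at 8.94 ± 0.928 against 3.02 ± 0.593 FPKM (1.31 ± 0.15, limma-trend adjusted p = 0.000927), and Dlx1, a transcription factor gene of GABAergic neuron precursors, at 4.53 ± 0.678 against 1.10 ± 0.484 FPKM (1.41 ± 0.20, adjusted p = 0.00351). The synaptic vesicle gene Syt1 (0.78 ± 0.13, adjusted p = 0.00661) and Stmn2 (0.62 ± 0.15, adjusted p = 0.0328) completed the 5. Stmn2, named after its value was seen, kept its call only with female 4 left out. Outside the list, 3 genes were among those with the smallest p of all. Synpr, a synaptic vesicle gene, stood at 50.6 ± 6.92 against 19.6 ± 2.15 FPKM (1.32 ± 0.11, adjusted p = 0.000114), Serpini1, the neuroserpin gene, at 20.7 ± 2.52 against 6.91 ± 1.13 FPKM (1.46 ± 0.13, adjusted p = 0.00023), and Dlx6as at 7.89 ± 0.825 against 2.12 ± 0.210 FPKM (1.51 ± 0.13, adjusted p = 0.000212). Dlx6as is an antisense gene, and whether the authors' counting used strand is not given in the sources used here. The list passed the set test (camera adjusted p = 0.000712; adjusted p = 0.0863 with an estimated correlation). Microglia markers differed in the other direction between these cultures (median -1.43, 14 of 17 called). Its median was 0.17 without male 1, 0.16 without male 1 and female 3, 0.13 without female 4 and 0.14 with a pseudocount of 5. In the list of ion channel, synapse and adhesion genes that OPCs share with neurons, 1 of 31 members was higher in male (Gria1) and 1 in female cultures (Nlgn2), with the same counts adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.0733). It passed towards female cultures at a mean of at least 5 FPKM (0.00442), with male 1 and female 3 as a batch term (0.043), and without male 3 (0.0307), male 4 (0.0347) or female 3 (0.0166). Gria1 lost its call without male 3, male 4 or female 1 and Nlgn2 without female 4.

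Mitochondrially encoded genes were higher in female cultures. Together the 13 such genes made up 19.9 ± 0.617% of all FPKM in male and 26.0 ± 1.91% in female libraries (exact two-sided permutation test, p = 0.0286). Of 12 members on the list 11 were higher in female cultures (11 adjusted over the list alone), with a median log2 difference of -0.53. The complex I subunit gene Mt-nd5 stood at 1545 ± 116 against 2736 ± 409.8 FPKM (-0.82 ± 0.10, limma-trend adjusted p = 0.00171), Mt-nd6 at 1856 ± 177 against 3206 ± 376 FPKM (-0.79 ± 0.09, adjusted p = 0.00113) and Mt-nd4l at 1927 ± 246 against 3269 ± 192 FPKM (-0.77 ± 0.09, adjusted p = 0.00116), the last of which lost its call after quantile normalization. Mt-nd4 stood far lower, at 51.3 ± 2.30 against 84.1 ± 10.8 FPKM (-0.69 ± 0.09, adjusted p = 0.00203). It overlaps Mt-nd4l, and how the authors' counting shared fragments between them is not given in the sources used here. The exception was Mt-nd3, named after its value was seen, at 4352 ± 344 against 4187 ± 441 FPKM (0.06 ± 0.08, adjusted p = 0.749), whose difference changed sign after quantile normalization (-0.15, adjusted p = 0.0220). The list passed the set test (camera adjusted p = 9.02e-12; adjusted p = 0.129 with an estimated correlation). Microglia markers were higher in female cultures as well (median -1.43), and neuron markers had a median of 0.28 (camera adjusted p = 0.0863 with an estimated correlation). By contrast, none of 53 nuclear-encoded genes of oxidative phosphorylation was called by limma-trend, over all genes or adjusted over the list alone. Of these, 11 had an unadjusted p under 0.05, where 2393 of all 11263 tested genes did. Towards male cultures 2 of the 53 were called without female 3 or with male 1 and female 3 as a batch term, and 1 without both. Their median was 0.067, and the lowest adjusted p was that of the cytochrome c gene Cycs (123 ± 10.1 against 97.9 ± 11.2 FPKM, adjusted p = 0.0644). The list median was 0.016 without male 1, 0.10 without male 4, 0.033 without female 1 or after rescaling, 0.13 without female 3, 0.024 after quantile normalization and -0.0047 with relative depth. Their set test was past the threshold towards male cultures (camera adjusted p = 0.0211; adjusted p = 0.771 with an estimated correlation). It was not past it without male 1 (0.737), without female 1 (0.41) or after quantile normalization (0.357), and changed sign with relative depth as a covariate (0.836). In male 1 and female 3, picked for deviating together, both lists were higher than in the other libraries. Medians were 0.21 (camera adjusted p = 1.61e-05) and 0.17 (5.37e-19), and these p-values are only descriptive. After quantile normalization the median of the mitochondrially encoded list was -0.16 and 5 members were called. Leaving out male 2, male 3, male 4 or female 4 left 6 called.

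**Figure D2:**
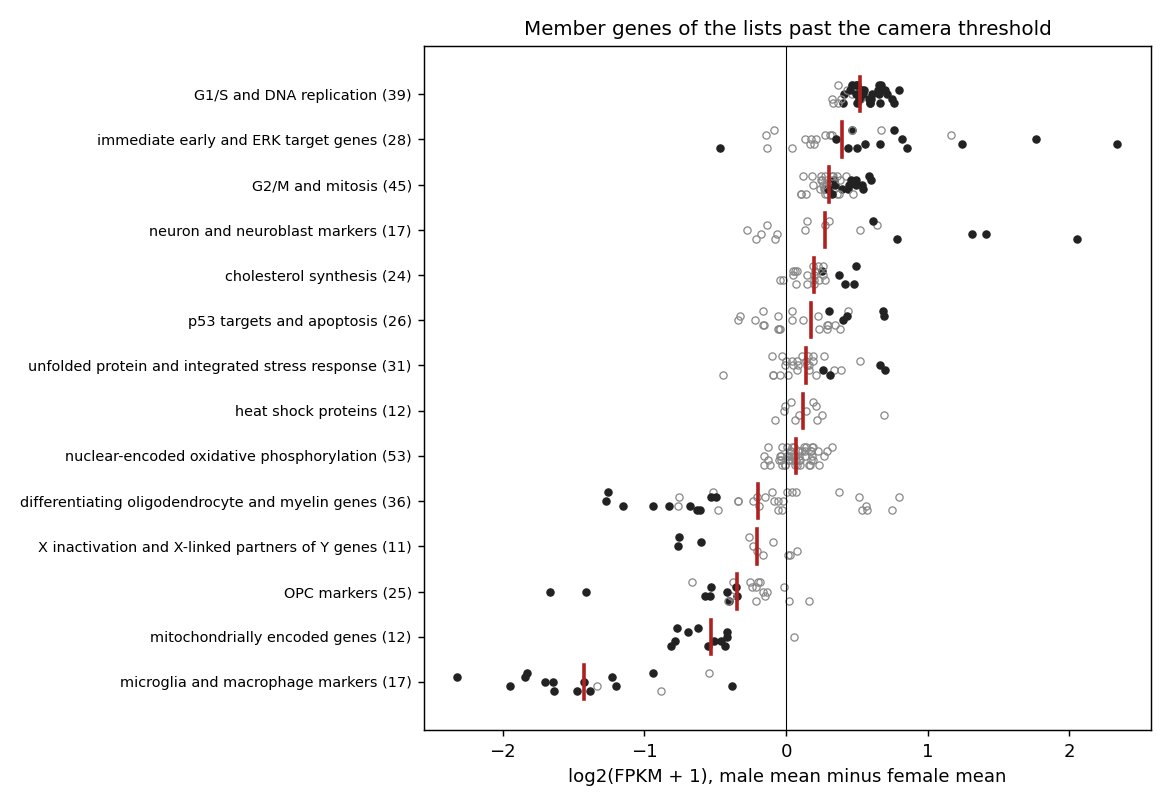
Log2 difference, male minus female on the log2(FPKM + 1) scale, of each member of the 14 lists past the camera threshold, with the number of genes tested in brackets. Points are genes, filled where limma-trend called them at an adjusted p under 0.05, and the red lines are list medians, which run from -1.43 for microglia and macrophage markers to 0.52 for G1/S and DNA replication.

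Smaller differences towards male cultures were found for cholesterol synthesis and for stress genes, beside medians of -1.43 for microglia and 0.28 for neuron markers (camera adjusted p = 0.0863 with an estimated correlation for the latter). Of 24 cholesterol synthesis genes 5 were higher in male and none in female cultures (10 and 0 adjusted over the list alone), with a median log2 difference of 0.20 (camera adjusted p = 7.15e-07; adjusted p = 0.166 with an estimated correlation). Among them were Idi1 (102 ± 10.3 against 72.7 ± 7.61 FPKM, limma-trend adjusted p = 0.0144), Acat2, Ebp and, named after its value was seen, Hmgcs1. Each of these lost its call with some library left out, and without male 2 or without male 3 none of the 24 was called. It was 2 without male 4 or with relative depth as a covariate, 3 without female 1 or female 2 and 1 without female 4. Among 31 genes of the unfolded protein and integrated stress response 4 were higher in male cultures (7 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00097; adjusted p = 0.121 with an estimated correlation). These were Atf4, the transcription factor gene of the integrated stress response (75.2 ± 9.02 against 47.0 ± 5.65 FPKM, 0.66 ± 0.10, adjusted p = 0.00552), and the amino acid and one-carbon enzyme genes Mthfd2 (0.70 ± 0.14, adjusted p = 0.0157), Shmt2 and Psat1. Shmt2 kept its call only without male 1 or female 3 and Psat1 only without female 3, and 2 of the 31 were called without male 2, male 3, male 4, female 1, female 2 or female 4, with relative depth as a covariate or after rescaling to the same total over genes that are not mitochondrially encoded. With male 1 and female 3 as a batch term 7 were called. The median was 0.076 without female 1, 0.086 without female 2 and 0.073 with relative depth. Of 26 p53 targets and apoptosis genes 16 had a positive log2 difference and 5 were called as higher in male cultures (5 and, in female cultures, 1 adjusted over the list alone), with a median of 0.17. The cell cycle inhibitor gene Cdkn1a stood at 242 ± 19.3 against 149.9 ± 19.1 FPKM (0.69 ± 0.09, adjusted p = 0.00252), and Plk2 (0.69 ± 0.12, adjusted p = 0.00705), Phlda3 and Ccng1 were also called. Phlda3 and Ccng1 lost their calls without male 2, male 3, female 1 or female 4, and Ccng1 also without male 4. Called members numbered 2 without male 2, male 3, female 1 or female 4 or with relative depth, and 3 without male 4, with no filter, after quantile normalization or after rescaling. The median was 0.11 without male 2, without female 1 or with no filter, 0.041 at a mean of at least 5 FPKM and 0.10 with a pseudocount of 5. The set test of this list was close to the threshold (camera adjusted p = 0.0453; adjusted p = 0.349 with an estimated correlation) and not past it without male 2 (0.131), female 1 (0.122) or female 3 (0.0556). None of 12 heat shock genes was called by limma-trend, over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, 1 was called without female 1, and Hspd1 (218 ± 1.06 against 192 ± 11.1 FPKM, adjusted p = 0.0892) came closest. Their median was 0.079 after quantile normalization and 0.19 without male 1 and female 3. Their set test (median 0.12, camera adjusted p = 0.0453; adjusted p = 0.129 with an estimated correlation) was not past the threshold without male 2 (0.0736), male 3 (0.0583), female 2 (0.0684) or female 3 (0.0576).

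The remaining lists were not past the threshold of the set test, and in most of them single genes were called. Over all 11263 tested genes 680 were called and 2393 had an unadjusted p under 0.05 (limma-trend). Single calls in a list therefore need not be particular to it. Of 39 genes of cell migration and axon guidance 6 were higher in female and 1 in male cultures (9 and 3 adjusted over the list alone; camera adjusted p = 0.0733). The guidance gene Sema5a stood at 9.44 ± 1.08 against 28.9 ± 7.53 FPKM (-1.49 ± 0.18, limma-trend adjusted p = 0.00126), the adhesion gene Tns3 at 14.8 ± 0.687 against 31.0 ± 7.40 FPKM (-0.99 ± 0.15, adjusted p = 0.00424) and the tetraspanin gene Cd9 at 26.6 ± 3.95 against 44.7 ± 5.80 FPKM (-0.73 ± 0.12, adjusted p = 0.00606), while the metalloproteinase gene Mmp15 was higher in male cultures (0.37 ± 0.06, adjusted p = 0.00853). The set passed towards female cultures at a mean of at least 5 FPKM (0.00442, median -0.20 against -0.099 with all tested genes), and without male 3 (0.0312), male 4 (0.0265) or female 3 (0.0231). With no filter on low values its median was 0.027, of the opposite sign. With 1 library left out the median ran from -0.049 (without male 1) to -0.16 (without female 3), and with relative depth it was -0.020. Without male 3, 3 members were called as higher in female cultures. Among lipid and extracellular matrix genes, the fatty acid hydroxylase gene Fa2h was higher in female cultures (2.69 ± 0.825 against 7.13 ± 1.44 FPKM, -1.15 ± 0.20, adjusted p = 0.00802), 1 of 23 (1 adjusted over the list alone; camera adjusted p = 0.35), and of 16 matrix genes Emilin1 and Eln were higher in male and Timp3 in female cultures (3 and 3 adjusted over the list alone; camera adjusted p = 0.868, its sign opposite to that of the median). Timp3 lost its call without male 3 or female 4, and Eln without male 2, male 3, male 4, female 1 or female 4. Of 25 glycolysis and hypoxia genes Ldha was higher in male cultures and Ddit4, Mxi1 and Kdm3a in female ones (2 and 3 adjusted over the list alone; camera adjusted p = 0.85). Ddit4 (42.4 ± 5.60 against 64.9 ± 6.11 FPKM, -0.61 ± 0.10, adjusted p = 0.00759) kept its call with each library left out in turn. Kdm3a lost it with any library left out, and Mxi1 and Ldha without male 2, male 3, male 4, female 1, female 2 or female 4. Mt3, the gene of a metal-binding metallothionein, was higher in male cultures (683 ± 36.1 against 373 ± 85.9 FPKM, 0.90 ± 0.14, adjusted p = 0.00618) and with Prdx1 was 1 of 2 antioxidant genes called of 27 (3 higher in male and 1 in female cultures adjusted over the list alone; camera adjusted p = 0.278). Prdx1 lost its call without male 2, male 3 or female 4. The complement gene C3 was higher in female cultures (0.914 ± 0.218 against 3.68 ± 0.896 FPKM, -1.28 ± 0.20, adjusted p = 0.00515), 1 of 6 inflammatory genes tested (1 adjusted over the list alone; camera adjusted p = 0.278). Notch1 was higher in female cultures (12.6 ± 1.15 against 20.8 ± 3.83 FPKM, adjusted p = 0.0133), 1 of 20 Notch, BMP and Wnt genes (2 adjusted over the list alone; camera adjusted p = 0.868, its sign opposite to that of the median). Of 9 sex steroid genes tested the peroxisomal enzyme gene Hsd17b4 was higher in female cultures (48.4 ± 3.64 against 65.8 ± 5.45 FPKM, adjusted p = 0.0123), with 1 gene higher in each sex adjusted over the list alone. The camera adjusted p of that list was 0.868, again opposite in sign to its median, and the estrogen receptor gene Esr1 was at or near 0 in all libraries. None of 9 interferon response genes (camera adjusted p = 0.757) and none of 66 ribosomal protein genes (camera adjusted p = 0.908) was called by limma-trend, over all genes or adjusted over the list alone, while 0 and 2 had an unadjusted p under 0.05. Ribosomal protein genes were higher in male 1 and female 3 than in the other libraries (median 0.20, camera adjusted p = 8.82e-30). As these libraries were picked for deviating together, that p-value is only descriptive. The set test of ribosomal protein genes between the sexes passed towards female cultures without male 1 (0.0153) and with relative depth as a covariate (7.08e-06).

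**Figure D3:**
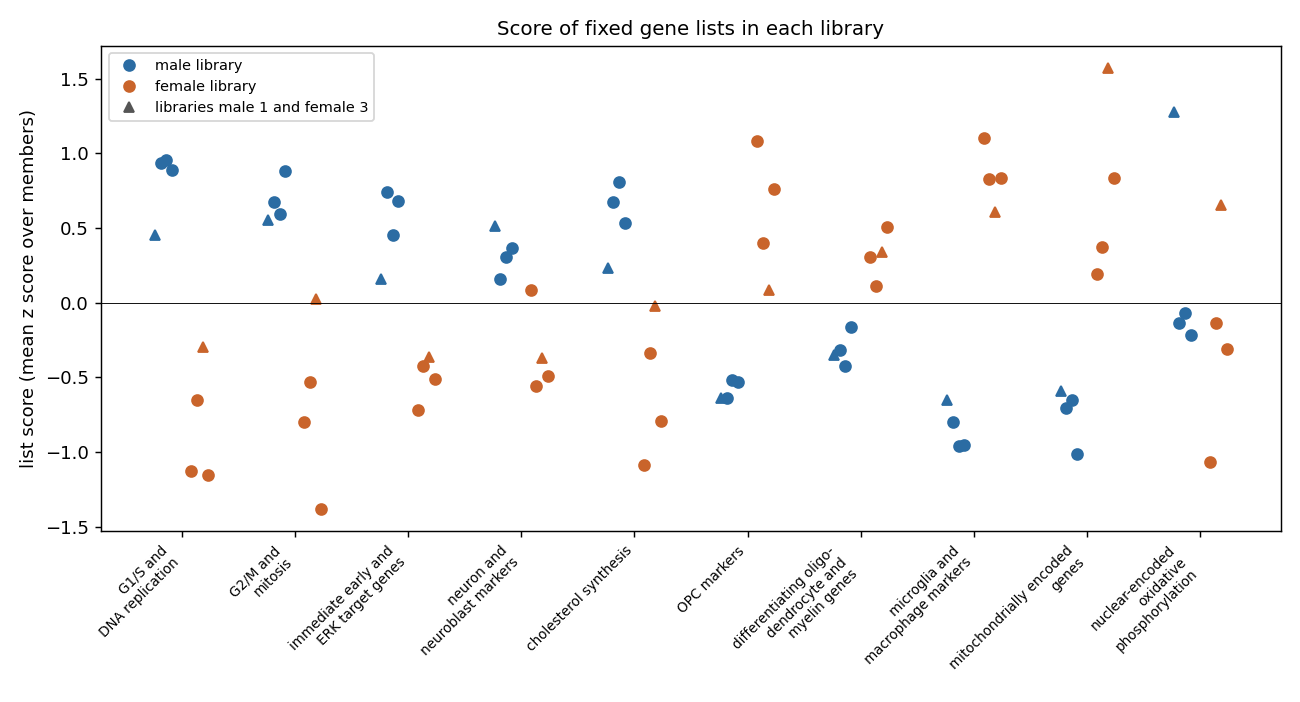
Score of 10 gene lists in each library, the mean over list members of the gene-wise z score of log2(FPKM + 1). Points are libraries, with triangles for male 1 and female 3, and the sexes do not overlap for the first 9 lists, while for nuclear-encoded oxidative phosphorylation the highest scores are those of male 1 (1.28) and female 3 (0.65).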

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

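Tests chosen only after the result was seen were the splits of the libraries for the gene counts and for the X-linked set, the OPC marker test of dilution, the comparison with nuclear-encoded oxidative phosphorylation genes, the share of mitochondrially encoded FPKM, and every fit without male 1 and female 3, with relative depth, or rescaled.

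Higher G1/S and DNA replication genes in male cultures were weighed first. Without the libraries male 1 and female 3, which stand apart, the list median was 0.622, against 0.52 with them. The difference thus does not rest on these libraries. They are of different sex, so a deviation they share shifts both groups alike, and leaving them out could not test it as a cause. Dilution of female precursors by microglia alone would lower OPC markers in female cultures too, but their median was -0.344, higher in female cultures. Members such as Gpr17 also change with lineage stage, which could mask dilution, so the list cannot decide on it. A later lineage stage of the female cultures stays open, since a list of 10 committed precursor genes had a median of -0.190, short of the -0.2 set beforehand, and did not pass (limma's camera, adjusted p = 0.134 over 4 added lists). A difference that comes from the sex of the animals also stays open and untested.

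Higher microglia and macrophage markers in female cultures were weighed next, against more microglia in those cultures, which the collection of non-adherent cells may carry over. A second microglia list, with no gene in the fixed lists, had a median of -0.787, with 5 of 6 log2 differences negative and 2 genes called (camera adjusted p = 0.00191 over 4 lists; adjusted p = 0.059 with an estimated correlation, not past the threshold), outside the interquartile range of the first list (-1.70 to -1.20). Rac2 (1.42 against 3.98 FPKM) and Alox5ap (0.448 against 1.90 FPKM), named after their values were seen, were those called, and Coro1a, the most abundant, was level at 8.28 against 7.998 FPKM. Most of this list lies near the filter, so the explanation stays open. The labels give no count of cells, and a difference in microglial expression between the sexes stays open as well.

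Higher mitochondrially encoded genes in female cultures were weighed last. A single scaling factor per library is argued against by the share of these genes within a library, which no such factor can alter and which was 6.12 percentage points higher in female cultures, without overlap. The list median was -0.435 without male 1 and female 3, so the difference does not rest on them. A deviation that these libraries share would shift both sexes alike and was not tested this way. The nuclear-encoded median of 0.067, known before this comparison was chosen, argues against a rise of oxidative phosphorylation genes as a whole. It was 0.016 without male 1 and -0.0047 with relative depth as a covariate, neither clearly towards female cultures. Rescaling to the same total over all other genes (-0.565) multiplies every gene of a library alike and so tests no other form of the authors' scaling, which stays open, and quantile normalization, which ties the most abundant genes to one scale, gave -0.16. Library preparation may also shift these genes, and neither it nor a sex difference in mitochondrial content could be tested.

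Of the 35 splits of the 8 libraries into 4 and 4, the real one gave 680 genes and the highest other 5. Only 1 of 35 gave as many, which is the smallest share this test can give, and every other split mixes the sexes. The libraries thus group by sex more than by any other split. As they may not be separate animals or litters, chance differences between animals, litters or cultures cannot be excluded. Outside the X and Y chromosomes the real count was 656 and the highest other 5, again 1 of 35. Splits other than the real one passed a median of 6.5 lists with the preset correlation, from 0 to 14. For lists, 2 of 35 splits gave 14, the other being male 1, male 2, male 3 and female 3 against the rest. That split keeps male 1 and female 3 together, and with both as a batch term 14 lists passed, while without both 13 did. The same split also keeps male 1, male 2 and male 3 together, and so holds part of the difference between the sexes. Splits with 2 male libraries on each side passed 0 to 7 lists, and the others apart from the real one 8 to 14. The test can therefore neither exclude chance for the lists nor show that chance alone gives 14. For the X-linked set 30 of 35 splits gave a camera p as small as 0.688, the smallest other being 0.00731, so chance cannot be excluded.

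A library was flagged against the other 3 of its sex in 23 of 371 groups tested. Chance gives about 1 in 20, which is close to this share, so most flags may be chance. The test sets the gap to the nearest library against the whole range, so small gaps are flagged where the other 3 nearly coincide, as for Hspd1. Among list scores, male 1 stood at 0.453 for G1/S genes (others 0.889 to 0.955), 1.28 for nuclear-encoded oxidative phosphorylation (-0.216 to -0.0668), 0.506 for antioxidant genes (-0.0327 to 0.0407) and 0.762 for interferon genes (-0.149 to -0.0325). Male 4 stood at 0.274 for extracellular matrix genes (-0.116 to -0.0718). The gene AC095947.2, named after its values were seen, stood at 12.78 in male 1 and 11.90 in female 3 on the log2(FPKM + 1) scale and was listed at 0 in the other 6 libraries. On that scale, male 1 also stood apart for Mt-nd6 at 11.05 (others 10.78 to 10.81), Plk2 at 4.34 (4.73 to 4.78) and Ccng1 at 7.48 (7.75 to 7.79). Female 3 stood apart for LOC100361008 at 0.78 (listed at 0 in the others), Sdhd at 7.57 (7.21 to 7.26) and Spry2 at 6.41 (6.17 to 6.21). Female 1 did so for Eif2s3 at 7.55 (7.68 to 7.71), Eln at 3.20 (3.49 to 3.53), Mxi1 at 4.70 (4.52 to 4.54) and Cryab at 3.65 (2.18 to 2.36). Male 3 did so for AABR07028795.1 at 2.20 (listed at 0 in the others), Cryab at 3.73 (3.16 to 3.22) and Dkk3 at 2.55 (2.43 to 2.44). The remaining ones were Mthfd2 in male 2 at 4.93 (4.36 to 4.45), Hspd1 in male 4 at 7.79 (7.77 in the others) and Syt1 in female 2 at 3.51 (3.70 to 3.74).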

How the results depend on the processing

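Settings chosen after seeing the data were those without male 1 and female 3, with a batch term for them, with relative depth, rescaled without mitochondrial genes, the pseudocounts and quantile normalization for lists, named genes and the X-linked set, and for that set also no filter and the replicate block. All 680 called genes that could be measured kept their direction under every setting, except 3 under quantile normalization. Direction could not change with the threshold of 0.1, the test against a 1.5-fold change, the replicate block or the batch term, which leave the differences as they were. The other settings reuse the libraries in which the genes were called, so kept directions are weak evidence. Counts of called genes stayed within 1.5 times of 680 with a pseudocount of 0.1 (655) or 5 (696), no filter (535), a mean of at least 5 FPKM (692), quantile normalization (715), male 1 and female 3 left out (882) or as a batch term (883), and rescaling (650). They moved further with an adjusted p threshold of 0.1 (1149, and 1113 outside X and Y), a test against a 1.5-fold change (18 and 16) and relative depth as a covariate (367 and 352), and ran from 296 to 808 (287 to 778) with 1 library left out. More genes were called without male 1 (714) or female 3 (808) and fewer without any other library. A looser threshold raises and a stricter test lowers counts by construction, and for left-out libraries and depth the cause was not tested.

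With the replicate block 397 genes were called (384 outside X and Y), and the heat shock list was not past the threshold (0.0598). Deviations of same-numbered libraries correlated at -0.12, 0.21, -0.18 and 0.04, which neither shows nor excludes a pairing by number.

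With an estimated correlation 1 list passed, the microglia list. Adjusted p for those that no longer did were 0.0863 for G1/S, differentiating oligodendrocyte, immediate early and neuron lists, 0.104 for OPC markers, 0.121 for the unfolded protein response, 0.129 for X partners, G2/M, mitochondrially encoded and heat shock genes, 0.166 for cholesterol synthesis, 0.349 for p53 targets and 0.771 for nuclear-encoded oxidative phosphorylation. By fry p53 targets had 0.0564 and nuclear-encoded oxidative phosphorylation 0.535. The latter had 0.357 after quantile normalization, the opposite sign with relative depth (0.836), and 0.000232 to 0.737 with 1 library left out. Heat shock genes had 0.0512 with no filter, 0.103 after quantile normalization, 0.0646 without male 1 and female 3, 0.114 after rescaling, and 0.0186 to 0.0736 with 1 library left out. For p53 targets it was 0.0520 with no filter, 0.124 at a mean of at least 5 FPKM, 0.0631 with the batch term, and 0.00788 to 0.131 with 1 library left out. The cause was not tested. Mt-nd3 changed sign after quantile normalization (-0.15, limma-trend adjusted p = 0.0220). The exact p of the first component was 0.1 without male 1 and female 3, the smallest that 3 against 3 allow. Of the remaining comparisons of named genes with the settings, 2524 kept their side of the threshold, 233 lost the call and 40 gained it. Alternatives planned for counts (other size factors, count models and voom) were not run because the values are FPKM. Depth limits the low genes most, as the shallowest library had 0.303 of the depth of male 1.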

Other observations

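The lists of this part were written after the fixed lists had been tested and before their own values were seen. Meis2, Scg5, Rap2a, Uchl1 and Syn1 were named after their values were seen. None of their genes is in a fixed list. Of 8 tested genes of GABAergic neurons 7 had a positive log2 difference and 2 were called, with a median of 0.391 (camera adjusted p = 0.00129 over 4 lists; adjusted p = 0.099 with an estimated correlation, not past the threshold). Called members included the transcription factor gene Meis2 (29.7 ± 2.42 against 21.4 ± 2.21 FPKM, limma-trend adjusted p = 0.0217), which lost its call without male 3, male 4 or female 2 (adjusted p up to 0.0744). Of 16 genes shared by most neurons 12 had a positive log2 difference and 2 were called, with a median of 0.122 (camera adjusted p = 0.0264; adjusted p = 0.189 with an estimated correlation). Called members included Scg5 (1.95 ± 0.445 against 0.534 ± 0.122 FPKM, adjusted p = 0.0223), which lost its call without male 1, male 3, male 4 or female 4 (adjusted p up to 0.0809). Abundant members such as Uchl1 (352 against 345 FPKM) and Syn1 (42.5 against 43.0 FPKM) were not called. More GABAergic neurons in the male cultures had been set beforehand to need both medians above a fixed level. The median of 0.122 of genes shared by most neurons fell short of it, so that explanation stays open. Of 10 committed precursor genes Rap2a was called, higher in female cultures (43.4 ± 1.45 against 57.1 ± 6.02 FPKM, adjusted p = 0.0231), and lost without male 2, male 3, male 4, female 2 or female 4 (up to 0.0793).

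Male 1 and female 3 were set against the other 6 libraries after their deviations were seen. The gene AC095947.2 was listed at 7042 FPKM in male 1, 3818 FPKM in female 3 and 0 in the other 6 libraries. Their deviations from their own groups correlated at 0.408, and the next highest of the pairs between the sexes at 0.210. These were the deepest libraries, female 3 having 0.981 of the depth of male 1.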
